A study of Mus musculus with 12 samples.

How the data were processed

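The series held 12 sequencing libraries from somatosensory cortex of mice 2.5 months old, in 4 groups of 3 defined by genotype and by antibody or input, per the labels. Tissue was dissociated with papain, nuclei were fixed with formaldehyde, and chromatin was cut with micrococcal nuclease and sonicated, per the labels' protocols. Groups were taken from the sample titles and the treatment and genotype labels.

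Cutadapt, Bowtie2 2.4.4, MACS2 and the mouse build mm10 were named without roles or parameters, per the submitters' processing notes. Adapter trimming, alignment and peak calling are the usual uses of these tools, but filters, duplicate handling and the peak-calling command were not given in the sources used here. One list of broad peaks per genotype was deposited, and every library of a genotype named the same list, per the labels, which fits calling on pooled libraries with pooled input. Replicates could therefore not be compared, no test across replicates was run, and no p-value was computed. The peak names inside the deposited control list called it WT, whereas the labels gave floxed control genotypes.

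Each row of the deposited lists gave a position, a score, a fold enrichment, a −log10 p and a −log10 q. The fold enrichment deposited by the authors is a ratio of immunoprecipitated reads to the local background expected by the caller. The −log10 p and −log10 q values deposited by the authors are the caller's, before and after its adjustment over the genome. The score deposited by the authors equalled 10 times −log10 p cut to a whole number in 231 of 231 control peaks and 3490 of 3491 cKO peaks, and was not used further. The lowest −log10 p in the authors' deposited table was 3.08 for controls and 3.02 for cKO, as a p threshold of 0.001 without a q threshold would give. Most peaks carry high q-values, which calling at a p threshold would allow. A list's length depends on depth, on immunoprecipitation efficiency and on the input. Read depth per library and per pool was unknown. Folds and q-values were used mainly to describe, rank and filter peaks within a list. Some cuts and fold ratios were also set across both lists, although each was scored against its own background.

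Positions were converted to 1-based coordinates and annotated with a RefSeq gene table of GRCm38.p6, the assembly whose chromosome coordinates mm10 shares, with 49943 genes on chromosomes 1 to 19, X and Y, of which 21887 were protein-coding. The table gave gene starts and ends without strand or exons. The promoter, exon and intron shares fixed before the data were examined were therefore replaced by overlap with gene bodies and by distance of up to 1000 bp from a gene boundary, and a peak outside genes was named by the nearest gene boundary. Genome sequence, repeats and base composition were not analysed here.

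Peaks were compared by overlap of at least 1 bp. The overlap and the locations were set against 1000 random placements of the peaks on the same chromosome with the same width, drawn between the first and last annotated or peak base, with assembly gaps not excluded. Gene groups were compared by the number of genes whose body held a peak, against 10000 random lists of protein-coding genes matched on gene length in 50 bins. Genes and peaks are not replicates, so these ranges describe the lists. Shares carry Wilson 95% intervals and medians carry intervals from order statistics, both for counting error alone. A q-value under 0.05, a −log10 q of at least 2 and a −log10 q of at least 5 were used as classes.

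The comparisons, the 15 gene groups, the alternatives and the naming rule were fixed before the data were examined. The rule named, in each list and among peaks of 1 list alone, the 10 peaks of highest fold, the 5 widest peaks and the 5 protein-coding genes with the most peak bases, then up to 4 genes per group by fold, and Nsd1. The text prints the peaks of highest fold in full and the widest in part. Grouping of neighbouring peaks (at least 3 other peaks of either list within 100 kb), gene-dense windows (687 of 2714 windows of 1 Mb) and the peaks of highest −log10 q were added afterwards. The alternatives were a −log10 q of at least 2, a fold at or above the median of both lists together, autosomes alone, peaks under 5000 bp apart joined, other overlap rules, protein-coding genes alone, other gene windows, unmatched random lists and, added later, the lists without grouped peaks.

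The procedures were tested on simulated lists of the sizes of both lists, over 21887 protein-coding genes. Of 100 random control-sized lists, 93 lay inside the 95% range of gene overlap. Recovery of 100 of 100 planted overlaps was fixed in advance, since the planted peaks were drawn from the cKO list they were compared with. Of 300 tests of gene groups on random peaks, 27 lay outside their range, more often than a 95% range implies, and 14 of 15 groups were called after peaks were planted in 1 in 2 of their genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.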

Results

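Dimethylation of histone H3 at lysine 36 (H3K36me2), a mark deposited by methyltransferases that include NSD1, was profiled by chromatin immunoprecipitation and sequencing in somatosensory cortex of mice 2.5 months old. The labels described 12 libraries in 4 groups of 3: immunoprecipitated chromatin and input chromatin from control animals, and the same pair from conditional knockouts (cKO). The knockouts carried the genotype Nsd1Nex-cKO, in which Nex-driven Cre recombinase acts in postmitotic excitatory neurons of the forebrain. The controls carried floxed alleles, with 2 of each group of 3 labelled Nsd1fl/+ and 1 labelled Nsd1fl/fl. One peak list represented each genotype and was named in the labels of all 6 of its libraries, so values carried no replicate error. Read depth per library was unknown from the lists. Intervals on shares and ratios covered counting error and treated peaks as independent.

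Nsd1, the targeted gene (mm10, chromosome 13, 55209782 to 55318325), held 0 peaks in either list. The nearest cKO peak lay 33.4 kb away, at 55175866 to 55176343, with a fold enrichment of 3.11 and a −log10 q of 0.738. The control list had 0 peaks on chromosome 13. The lists hold peak positions rather than coverage over the floxed exon, so they do not check the deletion.

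The first comparison asked how H3K36me2 peaks differed between control and cKO cortex. The cKO list was the longer, with 3491 peaks over 1002 kb against 231 peaks over 83.5 kb in controls, a ratio of 15.1 in number and 12.01 in covered length. In cKO cortex the highest fold enrichments were found 4.74 kb from Actg1, which encodes gamma-actin (chromosome 11, 120340804 to 120340950, fold 5.998), and inside Pltp, a phospholipid transfer protein gene (chromosome 2, 164843569 to 164843729, fold 5.58). Rarb, a retinoic acid receptor gene, followed (chromosome 14, 16971272 to 16971424, fold 5.51), as did Vstm4 (chromosome 14, 32878654 to 32878820, fold 5.45). In controls the highest values were found near the long noncoding RNA gene Gm33053 (chromosome 9, 59185567 to 59185713, fold 4.08), in Litaf, which encodes a late endosomal membrane protein (chromosome 16, 10986447 to 10986593, fold 3.995), and in Nckap5 (chromosome 1, 126091961 to 126092115, fold 3.98).

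The remaining 6 of the 10 highest cKO folds lay near Bmpr2, a bone morphogenetic protein receptor gene (fold 4.96), near the pseudogene Gm5205 (4.82), near Pemt (4.77), near Gm30551 (4.66), in the kinesin gene Kif3c (4.60) and in the kinase gene Stk38 (4.57). The Kif3c peak (chromosome 12, 3376159 to 3376305) had the highest −log10 q of these 10, at 13.9. Each of the 10 had a q-value under 0.05, 5 lay in gene bodies, 0 overlapped a control peak, and the widest spanned 198 bp. The other 7 control peaks of highest fold lay near Zfp386 (3.76), Gm32196 (3.72), Gm5067 (3.63) and Gm25757 (3.61), in Ttc28 (3.58), and near the defensin gene Defa21 (3.55) and Gm22889 (3.54). Of the 10 control peaks, 0 had a q-value under 0.05 and 0 overlapped a cKO peak, and their −log10 q ran from 0.0687 to 0.732.

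Fold enrichment, each list being scored by the authors against its own background, had a median of 2.18 (95% interval 2.09 to 2.31, range 1.14 to 4.08) in the control list and 2.82 (2.81 to 2.84, range 1.13 to 5.998) in the cKO list. A q-value under 0.05 was reached by 23 of 231 control peaks (9.96%, Wilson 95% interval 6.73 to 14.5) and by 641 of 3491 cKO peaks (18.4%, 17.1 to 19.7). A q-value of 0.5 or more was carried by 157 control peaks (68.0%) and 1750 cKO peaks (50.1%). Peaks were narrow for a broad mark, with median widths of 294 bp and 250 bp. The widest control peak, 1624 bp, lay in Sfi1 (chromosome 11, 3183804 to 3185427), and the widest cKO peak, 2360 bp, lay in the long noncoding RNA gene 2700054A10Rik (chromosome 17, 13550718 to 13553077, fold 1.47). Among peaks with a −log10 q of at least 2, the lists held 20 and 374 peaks. The ratios of the cKO to the control list rose to 35.4 in number and 36.5 in covered length at or above the median fold of both lists together, and to 27.6 and 29.7 without peaks that had at least 3 others within 100 kb. The joint median fold, 2.81, lay near the cKO median of 2.82 and above the control median of 2.18. That cut therefore removed a larger part of the control list by construction, and its ratios carry no further support. The ratio in covered length fell to 7.27 with peaks under 5000 bp apart joined.

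**Figure D1:**
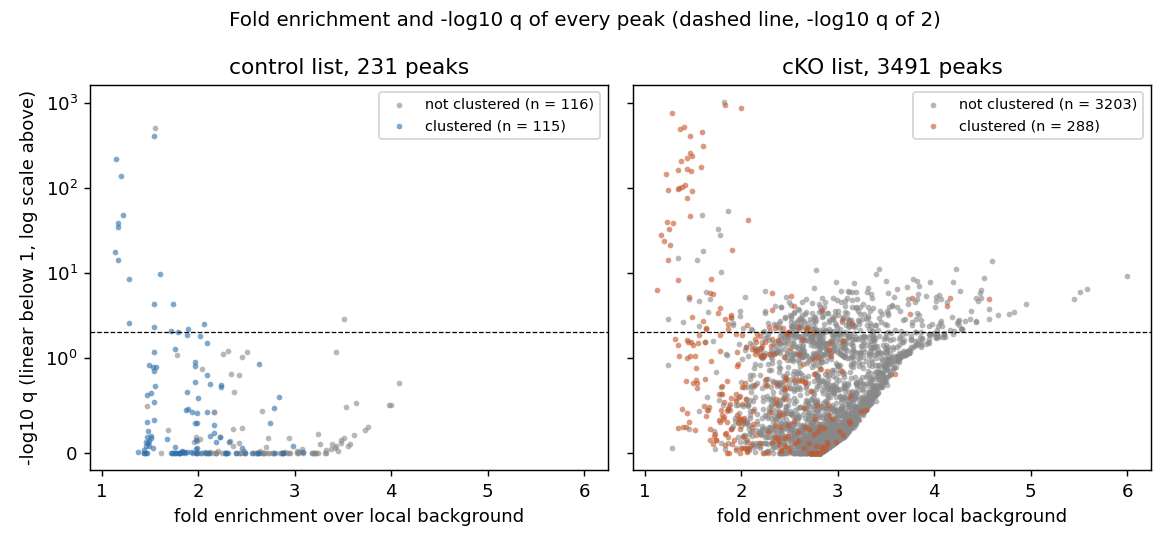
Fold enrichment over local background (horizontal axis) and −log10 q (vertical axis, linear below 1 and logarithmic above) of each of the 231 control peaks (left) and 3491 cKO peaks (right), with peaks that had at least 3 other peaks of either list within 100 kb in colour. Peaks with the highest −log10 q had folds below about 2.0 in both lists, and cKO peaks above the dashed line at a −log10 q of 2 extended to a fold of 5.998.

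The second comparison asked which peaks the genotypes shared. Of the 98 control peaks that overlapped a cKO peak, 60 lay in regions dense in peaks of either list, against 115 of all 231 control peaks. The overlapping cKO peak counted among the neighbours, so shared peaks met that condition more easily. The centrosomal protein gene Sfi1 (chromosome 11, 3131850 to 3203347) held 24 control peaks over 14576 bp, with folds of 1.37 to 1.72, and 23 cKO peaks over 12280 bp, with folds of 1.35 to 1.89. The nuclear body protein genes Sp110 and Sp140 and their neighbours Gm38510, C130026I21Rik and Gm7592 lay in a region of chromosome 1 (84924855 to 85624974) with 20 control and 42 cKO peaks. A region with Speer4d and Speer4c (chromosome 5, 15464160 to 15712175) held 16 and 15 peaks, and another with Speer4e and Gm10354 (chromosome 5, 14900152 to 15062266) held 11 and 14.

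At least 1 bp was shared by 98 of 231 control peaks (42.4%, 36.2 to 48.9) and 98 of 3491 cKO peaks (2.81%, 2.31 to 3.41), over 32441 bp. Random placement of the control peaks on the same chromosomes gave at most 3 that overlapped the cKO list in 1000 draws. Placement of the cKO peaks gave at most 2 that overlapped the control list. The 133 control peaks without a cKO overlap were led in width by a peak of 1055 bp in Gm51572 (chromosome 8, 55120434 to 55121488) and 1 of 968 bp in Sfi1, and the 3393 cKO peaks without a control overlap by 1 of 1947 bp in the pseudogene Gm20590 (chromosome 13, 74528689 to 74530635). With both lists restricted to a −log10 q of at least 2, 14 of 20 control peaks (70.0%) were overlapped, and 16 were overlapped by some peak of the whole cKO list. With both lists restricted to peaks at or above their joint median fold, 2.81, 0 of 53 control and 0 of 1878 cKO peaks were shared. Against the whole other list, 0 of those 53 control peaks and 7 of those 1878 cKO peaks were overlapped. The control peaks shared with the cKO list therefore all had folds below 2.81.

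Peaks with at least 3 other peaks of either list within 100 kb, a grouping chosen after the data were examined, made up 115 control peaks (49.8%) and 288 cKO peaks (8.25%). In 100 random placements such peaks numbered at most 5 and 34. These peaks formed 47 regions, of which 22 held grouped peaks of both lists, 25 held grouped cKO peaks alone and 0 held grouped control peaks alone. Several of the 25 were a single grouped peak, such as that at chromosome 11, 72351170 to 72351316. Ungrouped peaks were not counted, and a region of the X chromosome among the 25 (8007421 to 8231268) also held an ungrouped control peak. The Sfi1, Sp110 and Speer4d regions together held 64 control peaks (27.7%). Without the grouped peaks, 38 of 116 control peaks (32.8%) and 38 of 3203 cKO peaks (1.19%) were shared, against at most 2 in random placements.

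The 5 peaks of highest −log10 q in each list, also chosen after their values were seen, lay outside protein-coding genes. The first was in the long noncoding RNA gene Gm33838 (chromosome 9, 35305331 to 35305485 in the control list), with a −log10 q of 503 at a fold of 1.55 in controls and 1004 at a fold of 1.82 in cKO. The next was between genes on chromosome 2 (98662307 to 98662724 in the control list), with 402 at a fold of 1.54 and 929 at a fold of 1.83. A region of chromosome 9 without protein-coding genes (3000331 to 3038196) held 5 control and 26 cKO peaks, with median folds of 1.17 and 1.37. Of the 11 control peaks with a −log10 q of at least 5, 11 were overlapped by peaks of the whole cKO list and 0 lay in protein-coding genes. Of the 102 cKO peaks at that level, 19 were overlapped by peaks of the whole control list and 33 lay in protein-coding genes.

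The third comparison asked where peaks lay relative to genes. In cKO cortex 1685 of 3491 peaks (48.3%, 46.6 to 49.9) overlapped an annotated gene, and random placements gave a median of 48.3% (central 95%, 46.7 to 49.9). In controls 119 of 231 did (51.5%, 45.1 to 57.9, placements 43.3 to 56.3). Protein-coding gene bodies were overlapped by 39.3% of cKO peaks and 39.8% of control peaks, within the ranges of 38.6 to 41.5% and 35.1 to 48.5% from placements. Of the 374 cKO peaks with a −log10 q of at least 2, 154 overlapped them (41.2%, placements 35.6 to 45.7), as did 1263 of the 3203 cKO peaks outside grouped regions (39.4%, placements 38.3 to 41.9). Of the 302 cKO peaks that met both conditions, 139 did (46.0%, placements 34.8 to 45.7), and 21 of 1000 placements gave as many or more. Within 1000 bp of a protein-coding gene boundary lay 106 cKO peaks (3.04%, placements 2.92 to 4.12) and 15 control peaks (6.49%, placements 1.30 to 6.49).

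Gene-dense regions held more peaks than placements did. Windows of 1 Mb with at least 11 protein-coding genes, a class defined after the data were examined, held 1386 cKO peaks (39.7%, 38.1 to 41.3, placements 26.2 to 28.9) and 106 control peaks (45.9%, 39.6 to 52.3, placements 23.8 to 35.5), and 0 of 1000 placements gave as many in either list. Of the same 302 cKO peaks, 163 lay in such windows (54.0%, placements 22.8 to 32.5). Of the 20 control peaks with a −log10 q of at least 2, 5 lay in annotated genes (25.0%, 11.2 to 46.9, placements 30 to 75%) and 4 in gene-dense windows (20.0%, 8.07 to 41.6, placements 10 to 50%). Gene strand and exons were not used here, so promoter, exon and intron shares were not analysed here.

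**Figure D2:**
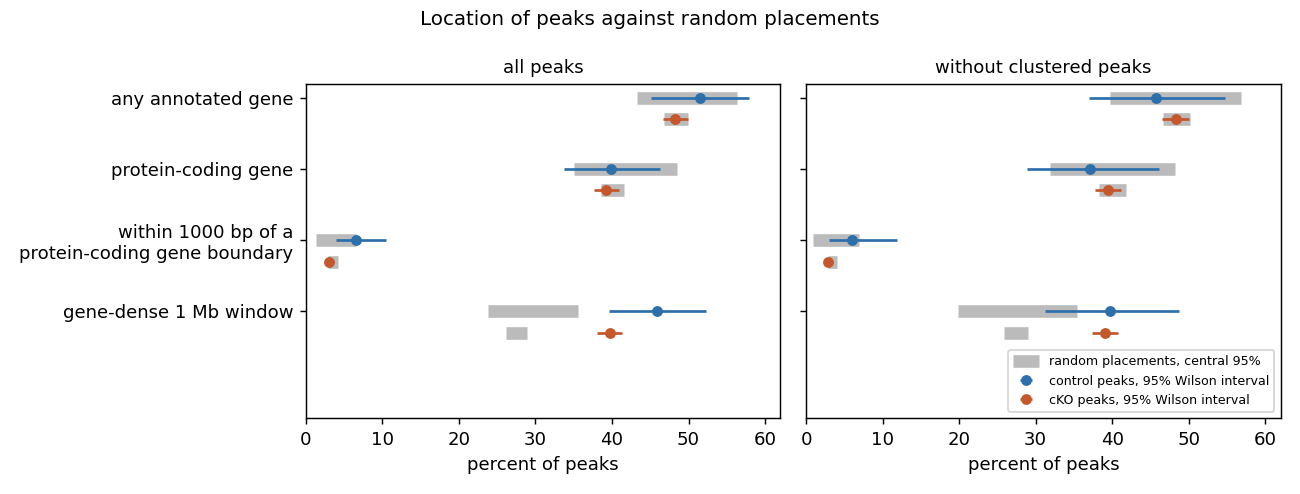
Percent of peaks (horizontal axis) in 4 kinds of location, for all peaks (left) and without grouped peaks (right, titled without clustered peaks), with points for the control and cKO lists, bars for Wilson 95% intervals and grey bands for the central 95% of 1000 random placements. The cKO points for gene-dense windows, at 39.7% and 39.0%, lay above their bands, and those for annotated genes lay inside.

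By chromosome, control peaks were concentrated on chromosome 5 with 40 peaks, chromosome 11 with 32 and chromosome 1 with 29, which carry the Speer4, Sfi1 and Sp110 regions. The cKO peaks were spread more evenly, from 1.85 per Mb on chromosome 7 and 1.67 on chromosome 5 to 1.03 on chromosome 15 among autosomes. The X chromosome held 164 cKO peaks, or 0.960 per Mb against 1.36 on autosomes, a ratio of 0.707 (0.604 to 0.827). Without grouped peaks the cKO ratio was 0.656 (0.554 to 0.777). Among cKO peaks with a −log10 q of at least 2, of which 20 lay on X, it was 0.810 (0.518 to 1.27), an interval that includes 1. In controls 7 peaks lay on X, a ratio of 0.447 (0.214 to 0.932), which became 0.918 (0.435 to 1.94) without grouped peaks. The Y chromosome held 12 cKO peaks and 0 control peaks, and the sex of the animals was not given in the sources used here.

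**Figure D3:**
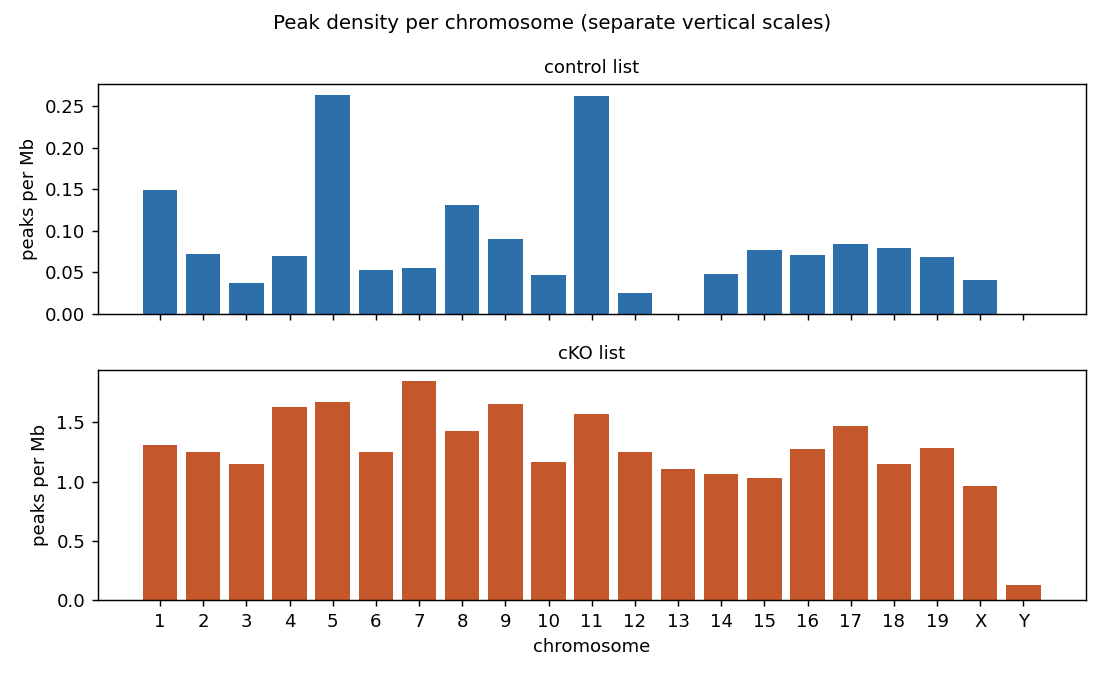
Peaks per Mb of annotated sequence (vertical axes, scaled separately) on each chromosome (horizontal axis) in the control list (top) and the cKO list (bottom), with 1 list per genotype. Control bars are highest on chromosomes 5 and 11, at 0.264 and 0.262 per Mb, and cKO bars on chromosome 7, at 1.85 per Mb.

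The fourth comparison asked which genes carried peaks, over 15 gene groups fixed in advance. Among synaptic adhesion and glutamate receptor genes, 13 of 29 held a cKO peak, led by the neurexin-family gene Cntnap5a (fold 3.43), Lrfn5 (3.21), the postsynaptic scaffold gene Dlg2 (3.07) and the cell adhesion gene Dscam (3.06). Among axon guidance genes 10 of 26 did, led by the guidance ligand genes Slit3 (3.40) and Slit1 (3.06), the netrin receptor gene Unc5d (3.30) and the ephrin receptor gene Ephb2 (3.04). Random lists of protein-coding genes of matched length gave 5 to 14 and 3 to 11 genes, so both groups lay within their ranges. In controls 1 gene over all 15 groups held a peak, Cadm2, a synaptic adhesion gene, with a peak at chromosome 16, 66961225 to 66961441, fold 2.10, that the cKO list shared at fold 2.11. It was a weak call in both lists, under a −log10 q of 2 and at 0.104 in cKO.

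Genes of cortical neuron identity lay within their matched ranges. Upper-layer and intratelencephalic neuron genes had 2 of 18 with a cKO peak, Unc5d and Cdh13 (2.73), and deep-layer genes 1 of 18, the transcription factor gene Foxp1 (2.89). Cortical area patterning genes had 0 of 18. The matched ranges were 0 to 6, 1 to 7 and 0 to 5. For area patterning genes a count of 0 could not lie below the range, and 5.54% of random lists had 0 as well. Inhibitory interneuron markers had 1 of 20, the potassium channel gene Kcnc2 (3.17), with a range of 0 to 5.

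Of the glial and vascular groups, oligodendrocyte lineage markers had 3 of 16 genes with a cKO peak (range 0 to 4), the transcription factor genes St18 (chromosome 1, 6664318 to 6664464, fold 4.37) and Tcf7l2 (2.91) and the myelin gene Mog (2.39). Astrocyte markers had 2 of 16 (0 to 4), the glypican gene Gpc5 (3.10) with 4 peaks and the bicarbonate transporter gene Slc4a4 (2.88). Microglial and vascular markers had 1 of 16 (0 to 4), the inositol phosphatase gene Inpp5d (2.71). Of the H3K36, DNA methylation and Polycomb machinery genes, 1 of 26 did (0 to 6), Kdm2b, which encodes an H3K36 demethylase (chromosome 5, 122977903 to 122978218, fold 3.25).

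Developmental Polycomb targets (30 genes), immediate early genes (17) and housekeeping genes (20) each had 0 genes with a cKO peak, within matched ranges of 0 to 4, 0 to 2 and 0 to 2. Ranges that start at 0 leave no room for a lower count, so fewer genes than random could not be shown for these groups. Olfactory and vomeronasal receptor genes had 9 of 1465 (4 to 16), led by Vmn2r36 (3.22), Vmn2r115 (3.19), Vmn2r62 (2.90) and Vmn2r60 (2.87). Clustered protocadherins had 0 of 57, below the matched range of 2 to 10. These genes overlap each other on chromosome 18 and cover 514 kb together, where 0.593 cKO peaks would fall at the density of that chromosome, with a Poisson chance of 55.3% for none. Over the 269 distinct genes of the 13 groups listed by name, 33 held a cKO peak, and 4 held 1 with a −log10 q of at least 2. These were St18 (−log10 q 2.87), Kdm2b (2.85), and the postsynaptic gene Dlgap1 (2.77) and Csmd1 (3.01), the last pair named because the count was small.

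**Figure D4:**
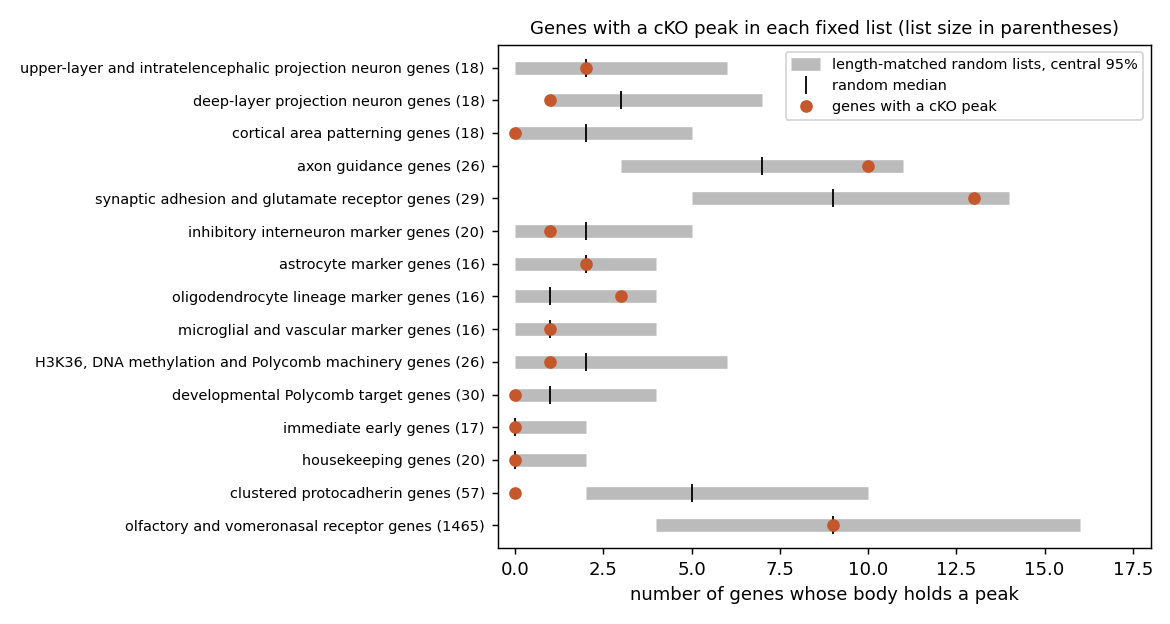
Number of genes whose body holds a cKO peak (horizontal axis) in each of 15 groups, with points for the cKO list and, for 10000 random lists of matched gene length, grey bands for the central 95% and ticks for the median. Among the 15 points, that of the clustered protocadherins, at 0 of 57, lies outside its band.

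Over all 21887 protein-coding genes, 57 held a control peak, 1197 held a cKO peak and 31 held both. Random genes of matched length gave 3 to 12 genes in both, and lists drawn independently would share 3.12. Sfi1, Sp140, Sp110, Gm38510 and C130026I21Rik had the most peak bases in controls, and in cKO Sfi1, Gm38510, C130026I21Rik, Sp140 and Gm7592 did. Genes with a cKO peak had a median length of 77.0 kb (71.1 to 83.8), against 15.9 kb in genes without and 99.6 to 117 kb for randomly placed peaks. Genes with a control peak had a median length of 51.8 kb (33.7 to 107), against 89.7 to 176 kb for placed peaks.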

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

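No paired analysis was possible because each genotype had 1 list without values per replicate, which also ruled out leaving out a replicate, and the wider promoter window was not run without gene strand. Leaving out grouped peaks and counting gene-dense windows were chosen after the data were seen. Of the alternative values for 15 results, 31 stayed within their interval or within 1.5 times the count, 34 did not, and of those for single gene groups 127 stayed and 23 did not. Control and cKO peaks numbered 20 and 374 at a −log10 q of at least 2 and 53 and 1878 at or above the pooled median fold, by construction fewer, and 116 control peaks were left without grouped peaks. The covered-length ratio was 36.5 at or above the pooled median fold, a cut near the cKO list's own median that raises it by construction. It was 29.7 without grouped peaks and 7.27 with peaks joined over 5000 bp. The overlapped shares of control and cKO peaks were 32.5% and 2.15% at a reciprocal 50%, 56.7% and 4.50% within 5000 bp, 70.0% and 3.74% with both lists restricted at once to a −log10 q of at least 2, 0% and 0% with both restricted to the pooled median fold or above, and 32.8% and 1.19% without grouped peaks. At the pooled median fold or above, 0 of the 53 control peaks overlapped any peak of the whole cKO list either. Median folds were 1.54 and 2.89 at a −log10 q of at least 2, and 2.67 and 2.85 without grouped peaks. With protein-coding genes alone, 39.8% of control and 39.3% of cKO peaks lay in genes. At a −log10 q of at least 2, 25.0% of the 20 control peaks lay in any annotated gene, below the placement median of 50% (central range 30 to 75%), whereas the whole list lay above its own. Gene-dense windows held 48.4% of cKO peaks at that level but 20.0% of control peaks, which turned from above the placement median to below it (30%, central range 10 to 50%). Random lists not matched on length put 1 group outside its range in the control list and 3 in the cKO list (axon guidance and synaptic genes above, olfactory and vomeronasal receptors below). The cKO list had 0 groups outside with at least 500 bp of gene body covered and 0 at a −log10 q of at least 2. In both of the latter settings the matched range of the clustered protocadherins began at 0 (0 to 3 and 0 to 2). Their count of 0 could therefore not lie below it. Median lengths of genes with a peak became 31.3 kb for control and 53.2 kb for cKO with 5000 bp added to each gene, and 65.6 kb for cKO at a −log10 q of at least 2. Apart from these constructions the cause was not tested. Depth was unknown, and the control list was too short above a −log10 q of 2 for shares in single locations.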

Other observations

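The tests in this part were all chosen after the results they bear on had been seen, and so were the regions named here. Several regions held groups of cKO peaks and 0 grouped control peaks, which by itself shows no genotype difference, since the cKO list was 15.1 times as long. In 100 random placements, drawn without regard to gene density, a median of 13 and up to 34 cKO peaks were grouped. The 288 observed cannot be set against that here, since they include the 22 regions with grouped control peaks. The largest such groups held 9 and 7 cKO peaks on the X chromosome (170809606 to 170857088 and 94878955 to 94972737), without protein-coding genes. A group of 5 lay in a region of chromosome 13 with Prl2c3. The regions below were picked from those with protein-coding genes. On chromosome 17 (mm10, 28919003 to 29104531) 5 cKO peaks with a median fold of 2.78 lay in a region with Stk38, the splicing factor gene Srsf3 and Cdkn1a, a cell cycle inhibitor gene. On the X chromosome (8007421 to 8231268) 5 peaks with a median fold of 2.83 lay in a region with Suv39h1, which encodes an H3K9 methyltransferase, and Rbm3. That region also held an ungrouped control peak (8045600 to 8045867, fold 2.66), which a cKO peak overlapped. On chromosome 6 (134689995 to 134724052) 4 peaks with a median fold of 3.21 lay in a region with Borcs5 and the phosphatase gene Dusp16, and on chromosome 4 (132161565 to 132230399) 4 peaks with a median fold of 2.83 lay in a region with Ythdf2 and Gmeb1.

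Some groups of peaks present in both lists lay among named gene families. A zinc finger gene region on chromosome 4 (147089100 to 147487530), with Zfp978, Zfp991, Zfp988 and Zfp982, held 3 control and 9 cKO peaks. A region of chromosome 15 (75085512 to 75168776) with Ly6c2, Ly6a2 and Ly6g held 3 and 2, and the Ugt1a region of chromosome 1 (88217325 to 88301322) held 1 and 5.

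The cKO list held 15.1 times as many peaks as the control list, although the deleted gene encodes an enzyme that deposits the mark. Weak calls near the threshold are argued against as the whole cause, since the ratio was 18.7 (11.97 to 29.2) at a −log10 q of at least 2, a looser p cut in the longer list, and 13.1 (8.46 to 20.4) at an equal −log10 p of at least 6.71 in the authors' deposited table (7.82, 4.22 to 14.5, at 10 or more, the lowest of 6 cuts). Those ratios cover grouped and ungrouped peaks together. Outside grouped regions the ratio was 26.8 (20.2 to 35.6) at a −log10 p deposited by the authors of at least 4. It was 33.6 (21.4 to 52.8) at 5 or more. At 6.71 or more it was 108 (29.5 to 396), but with 2 control peaks against 216. At 10 or more it was 45.0 (7.82 to 259), with 1 control peak. At −log10 p under 4 in the authors' deposited table and outside grouped regions, the median fold was 2.81 (2.81 to 2.82, n = 1890) in cKO and 2.68 (2.56 to 2.85, n = 67) in controls, which leaves a difference in expected reads per site open. Among the 11 shared peaks with a −log10 q of at least 5 in both lists, the cKO fold was 1.19 times the control fold (1.14 to 1.29), against 1.06 (1.02 to 1.11, higher in 67) over all 98 pairs, 1.03 (0.987 to 1.07) over the 60 grouped pairs and 1.13 (1.06 to 1.18, higher in 30) over the 38 others, but the 38 are 1.19% of the ungrouped cKO peaks and leave depth undecided. Depth, immunoprecipitation efficiency and input cannot be told apart from genotype with 1 list each, and an effect of Nsd1 loss stays open and untested.

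The most significant peaks had low folds in both lists, which would be consistent with reads piled up at repeats collapsed in the assembly. Control peaks with a −log10 q of at least 5 had a median fold of 1.20 (1.15 to 1.55, n = 11) against 2.23 (2.11 to 2.36, n = 220) in the rest. In cKO the same comparison gave 2.06 (1.69 to 2.99, n = 102) against 2.83 (2.82 to 2.84, n = 3389), which did not separate them, whereas those with a −log10 q of at least 10, 34 of 47 of them grouped, had 1.47 (1.38 to 1.59) against 2.83 (2.82 to 2.84, n = 3444). Outside grouped regions, cKO peaks with a −log10 q of at least 5 had a median fold of 3.33 (3.10 to 3.61, n = 58) against 2.85 (2.84 to 2.86, n = 3145), but selection by q raises fold where background is ordinary, and 18 of the 58, with the 8 of highest −log10 q among them (folds 1.35 to 1.86), lay below 2.85, so repeats stay open for that set. Repeat annotation was not used here, and no biological explanation was tested.

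The excess of cKO peaks in gene-dense windows did not come from grouped peaks at gene families alone, since without them 39.0% (37.4 to 40.7) lay there against 25.9 to 29.0% in placements. It did not come with peaks at gene boundaries either, where 2.90% (2.38 to 3.54) lay against 2.90 to 4.09% in placements. Base composition, mappability and nuclease preference could produce such an excess and stay open, since no sequence was used here. The control list had a share of 39.7% without grouped peaks (placements 19.8 to 35.3), but at a −log10 q of at least 2 its share was 20.0% (placements 10 to 50%, 20 peaks) against 48.4% in cKO (24.1 to 32.9). Those peaks are unlike in kind, since 18 of the 20 control peaks were grouped against 72 of the 374 cKO peaks, and a difference between genotypes was not tested.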
